A study of Homo sapiens with 16 samples.

How the data were processed

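The series describes m6A-eCLIP of U87, U87-R and U87-R treated with STM2457, made by a commercial provider from polyA RNA that was fragmented, immunoprecipitated with an m6A antibody and crosslinked, per the labels' protocols. U87 and the untreated U87-R carried a DMSO control label. Per the submitters' processing notes, UMI-tools, cutadapt and STAR were used and the build was hg38; their versions and settings, the base and peak callers and the normalization are not given in the sources used here.

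The authors deposited 1 list of called bases per eCLIP library, with a position, a strand and a score. The score is the smallest of 4 scores listed beside it, as the values show, and its formula is not given in the sources used here. A base that is not listed has no value. The deposited lists hold no read count and no coverage, so depth is unknown, a score cannot be turned into a methylation level, and a higher score can come from more methylation, more RNA or deeper sequencing. Scores reached a common ceiling of 708 in several libraries.

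The authors also deposited 1 list of reproducible sites and 1 of reproducible peaks per group. Per the deposited values, each gives the fraction of a group's libraries in which the site or peak passed, and a combined score. For sites this score equals the geometric mean of the libraries' scores, with at least 10 in each and at least 2 libraries, after a further filter that the sources used here do not describe. The meaning of the peaks' score is not stated, and it was used only to rank peaks within a list. Peaks are short, often adjacent tiles (median length 37, 38 and 44 bases for U87, U87-R and STM2457) that merged into 29905, 30933 and 20372 regions. Both kinds of list join the libraries of a group, so they have no replicate error. Their overlap was counted at the same base and strand for sites, and at 1 base or more on the same strand for peaks.

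Genes came from a table of RefSeq genes on GRCh38.p14, which has the coordinates of hg38 but neither strands nor exons, and no genome sequence was used. The strand of a gene was taken from its called bases, where at least 5 lay in its span alone and at least 80% of them were on 1 strand. Of 452349 bases called in any library, 378043 (83.6%) were given to 1 gene, 681 lay in 2 or more genes of their strand, and 73625 lay in no gene that had been given their strand. These last include bases inside genes to which no strand could be given, or of kinds other than protein-coding and long noncoding. Protein-coding genes were served before noncoding ones. This step can err where another transcript crosses a gene: ND6, KRT86, ADRM1, FRMPD1, GPC3 and ADGRE3 got the strand opposite to the one they are known to be read from, and other genes not named here may have too. Sequence motifs and transcript regions could not be computed, and the distance to the annotated 5′ end, chosen after seeing the data, was used in place of regions.

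Per gene, the scores of its bases were summed in each library. A gene without a called base in a library got a sum of 0 there. Where a gene is said below to be listed at 0, no base of it was called, and no 0 was measured. As the values were scores and not counts, the test written for that case before the data were examined was used: limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2(sum + 1), with 3 group means over the 8 libraries in 1 fit and Benjamini-Hochberg adjustment over 9835 genes with a sum of at least 10 in at least 2 libraries. Changes are on the log2(sum + 1) scale, which understates them for low sums, and no scaling between libraries was applied. For single bases the plan had no test for scores, so the same model was fitted to log2(score + 1) at 188742 bases called in at least 2 libraries of a group, with bases not listed set to 0. Gene lists were tested with camera at a preset correlation of 0.01, and with an estimated correlation and with fry. The 17 lists, fixed before the data were examined, were m6A machinery, DNA repair and alkylation damage, glioma stem and neural progenitor factors, mesenchymal and extracellular matrix, receptor tyrosine kinase, PI3K and MAPK signalling, cell cycle and p53 response, apoptosis and survival, drug transport and oxidative detoxification, hypoxia and glycolysis, stress response, interferon and innate sensing, immediate early and AP-1, chromatin regulators, WNT, BMP and Hippo signalling, long noncoding RNAs, housekeeping and ribosomal protein genes, and markers of other cell types. Numbers per library were compared with exact two-sided permutation tests, which cannot go below 0.1 in either comparison.

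Named genes followed a rule fixed before the data were examined: the 10 largest changes per direction among called genes with a called base in every library of the higher group and no overlap between the groups' libraries, up to 2 members per direction from each list, and MGMT, METTL3, SOX2, EGFR, MALAT1 and MAT2A in any case; for bases, the 5 largest changes per direction, 1 per gene. Some genes that the rule names are not reported here. On simulated data of 9835 genes with 100 planted changes of each size, the fit recovered 12% of changes of log2 1 and 55% of log2 2 between U87-R and U87 (3 of 70 calls false), and 9% and 43% under STM2457 (8 of 60 calls false). The real STM2457 comparison called 4390 genes, which makes its adjusted threshold looser. The last 2 percents therefore do not give the recovery of that comparison.

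Replicates carry the same numbers in each group. The deviations from the group means of U87 and U87-R libraries with the same number correlated at 0.102, 0.323 and 0.119. All were above 0.1, which was taken as a hint that the numbers pair these libraries, from the correlations alone. The main fits and the permutation tests did not use this pairing, and the replicate number entered only as a block in an alternative setting. The hint is thin, since U87 replicate 1 correlated at 0.132 with U87-R replicate 3, and U87 replicate 3 at 0.143 with U87-R replicate 1. Between U87-R and treated libraries the same-number correlations were -0.0107 and -0.0133, and these were not treated as pairs. No 2 libraries were copies of each other: identical scores made up at most 0.003% of the shared bases.

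Alternatives written before the data were examined covered the pseudocount, the filter, scaling, the block, the libraries in the fit, the sites summed, the score threshold, the overlap and leaving out each library. Added after seeing the data were median centring, median-of-ratios scaling, the number of called bases as the value, and limits on the score. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.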

Results

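The study mapped N6-methyladenosine (m6A), a common mark on messenger RNA, in 3 states of a glioma cell line. U87 MG (U87) is an established human glioma line, and U87-R is its derivative resistant to temozolomide (TMZ), an alkylating drug; U87-R was grown in medium with 50 µM TMZ. U87-R was also treated with 50 µM STM2457, an inhibitor of the m6A methyltransferase METTL3, for 96 hours. The labels list 16 samples, of which 8 were m6A-eCLIP libraries used here: 3 of U87, 3 of U87-R and 2 of U87-R with STM2457. In this assay an m6A antibody is crosslinked to fragments of polyA RNA, and the base bound is read from the sequencing. The 8 input libraries, which would measure RNA abundance, were not analysed here, so every value below joins the methylation of an RNA with its abundance.

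Each library was a list of called bases with a score. The U87 libraries held 150135, 171012 and 182556 called bases, the U87-R libraries 192697, 149477 and 170655, and the treated libraries 105900 and 110875. For 2 libraries of the same group, 40.6% to 43.0% of the bases called in either were called in both. This share was 39.6% to 41.8% between U87 and U87-R libraries, and 24.0% to 27.8% between a treated library and any library of another group. Unequal numbers of called bases lower this share by themselves. In a principal component analysis of the sums of scores per gene, the first component (53.1% of the variance) set the treated libraries apart, and the second (14.1%) parted U87 from U87-R. No reads or coverage were used, so depth is unknown and no counting error can be given. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

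The first comparison, U87-R against U87, asks what sets resistant cells apart from the parental line. All U87-R libraries came from medium with TMZ and all U87 libraries from medium without it, so a difference can belong to resistance or to the drug in the medium. MGMT, the repair enzyme that removes the guanine lesions left by TMZ, had no called base in any U87 library, and its sum of scores was 122 ± 31.2 (SD, n = 3) in U87-R, from a mean of 9.67 called bases. Several genes of the zinc finger family were called in U87-R and nearly absent in U87. LDOC1, a gene first described as lowered in cancer lines, went the other way, from 561 ± 82.2 in U87 to 0.249 ± 0.431 in U87-R (both SD, n = 3). With 3 libraries per line smaller changes would mostly be missed.

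The number of called bases was 167900 ± 16433 in U87 and 170940 ± 21611 in U87-R (SD, n = 3 each; exact two-sided permutation test, p = 1.0, smallest possible 0.1). The median score at the 30839 bases called in all 8 libraries was 38.1 ± 3.83 in U87 and 42.6 ± 5.17 in U87-R (SD, n = 3 each; exact two-sided permutation p = 0.4). Called bases within 50 nt of the annotated 5′ end of a gene numbered 9109 ± 1141 in U87 and 10570 ± 267 in U87-R, and 3.59% ± 0.172 and 3.29% ± 0.0990 of assigned called bases lay in genes of long noncoding RNAs (SD, n = 3 each; exact two-sided permutation p = 0.1 for both, the smallest possible). The authors' deposited lists of reproducible sites held 33396 sites for U87 and 35207 for U87-R, and 28016 stood in both, which is 79.6% of the U87-R list. Of the authors' 96528 reproducible U87-R peaks, 91.9% overlapped a U87 peak by at least 1 base on the same strand.

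Of 9835 genes tested with limma on log2(sum of scores + 1), 87 were higher in U87-R and 23 lower at a Benjamini-Hochberg adjusted p under 0.05, and 1205 had an unadjusted p under 0.05. Among the largest increases, ZNF875 rose by 7.67 ± 0.54 (log2, SE; adjusted p = 0.000738), INHBE, an inhibin subunit, by 7.39 ± 1.07 (adjusted p = 0.0106), and ZNF415 by 7.37 ± 0.62 (adjusted p = 0.00119). DOCK8, an exchange factor for small GTPases, was listed at 0 in U87 and at 149 ± 37.3 in U87-R (adjusted p = 0.000897), ZNF488 at 0 and 148 ± 84.4 (adjusted p = 0.00148), and ZNF83 at 0 and 125 ± 20.5 (adjusted p = 0.0012; SD, n = 3). MGMT (chromosome 10, 129467241 to 129770983, hg38) had an adjusted p of 0.00173. The sums given to KRT86 (284 ± 155 in U87-R, 4.40 ± 7.35 in U87) and ADRM1 (321 ± 225 and 1.58 ± 0.863) were also among the largest increases, but these genes are known to be read from the strand opposite to that of the bases, so the values belong to other transcripts.

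Among the genes lower in U87-R, LDOC1 fell by 8.86 ± 0.64 (log2, SE; limma adjusted p = 0.000738) and ACTL8, an actin-like gene, fell by 6.70 ± 0.68 (adjusted p = 0.00202). ESM1, which encodes the secreted proteoglycan endocan, fell from 223 ± 34.3 to 3.38 ± 2.84 (SD, n = 3; adjusted p = 0.00535). SAT1, an enzyme of polyamine catabolism, stood at 106 ± 79.6 in U87 and was listed at 0 in U87-R (adjusted p = 0.00492), and so was ZNF518B, at 62.6 ± 16.4 in U87 (adjusted p = 0.00698). The noncoding RNA LINC03125 fell by 6.16 ± 0.99 (adjusted p = 0.0191), and LINC02597 was listed at 0 in U87-R after 70.7 ± 48.3 in U87 (adjusted p = 0.00804). HCAR2 and HCAR3, receptors of hydroxy acids, and the ribosomal protein gene RPSA were also called lower, with adjusted p of 0.00934, 0.00754 and 0.00354. HCAR2 and HCAR3 are near-identical copies of each other and RPSA has many processed copies, so these values are uncertain.

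No fixed gene list passed the test between the lines (camera, lowest adjusted p over 17 lists 0.133). Of 25 tested genes of DNA repair and alkylation damage, 2 rose, MGMT and FANCD2. FANCD2, which acts in crosslink repair, was listed at 0 in U87 and at 32.1 ± 16.1 in U87-R (SD, n = 3; adjusted p = 0.00787). Adjusted over the list alone, 2 rose and 1 fell. Of 21 glioma stem and progenitor factors 1 rose, the transcription factor KLF4, by 2.25 ± 0.43 (log2, SE; adjusted p = 0.0494), and 2 adjusted over the list alone. Of 18 genes of hypoxia and glycolysis 1 rose, EGLN3, an oxygen-dependent prolyl hydroxylase, by 5.68 ± 0.70 (adjusted p = 0.00492), and 4 adjusted over the list alone. RPSA was the 1 gene that fell among 11 housekeeping and ribosomal protein genes, as it also was over the list alone. In the other 13 lists no member passed over all genes, and adjusted over the list alone 1 passed in each of 3 lists, those of mesenchymal and extracellular matrix genes, of stress response and of immediate early genes. METTL3 itself stood at 113 ± 14.9 in U87 and 187 ± 66.8 in U87-R (SD, n = 3; adjusted p = 0.443). EGFR (1592 ± 114 and 1680 ± 282), MALAT1 (3307 ± 686 and 2855 ± 701) and MAT2A (489 ± 36.9 and 489 ± 90.3) did not pass either, with adjusted p of 0.921, 0.735 and 0.987. SOX2 had no sum of its own, because its called bases did not meet the rule that assigns a strand to a gene.

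With the replicate number as a block, 60 genes were higher and 13 lower, and KLF4 was no longer called (adjusted p = 0.104). With each library centred on its median sum, 98 were higher and 58 lower, so the share of higher genes among those called fell from 79.1% to 62.8%. The count moved when a library was left out, and was 60 without U87 replicate 1, 56 without U87-R replicate 1, 55 without U87-R replicate 3, 128 without U87 replicate 2 and 161 without U87-R replicate 2. Both replicate 2 libraries stood apart on the third principal component (11.5% of the variance), at -47.8 and -82.4, where the other untreated libraries lay between 18.8 and 38.5. INHBE lost its call without U87 replicate 1, U87-R replicate 1 and U87-R replicate 3 in turn (adjusted p = 0.0628, 0.0677 and 0.0677). So did KRT86 (0.0691, 0.0668 and 0.0887), LINC03125 (0.0817, 0.0776 and 0.0831; also 0.0818 without U87 replicate 3) and KLF4 (0.152, 0.179 and 0.189; also 0.143 without U87 replicate 3). Their changes stayed large: over the left-out libraries INHBE ran from 6.70 to 8.69 (log2) and KLF4 from 1.93 to 2.66.

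At single bases, 1 of 188742 tested passed between the lines, in PIK3R6, a regulatory subunit of phosphoinositide 3-kinase. It lay on chromosome 17 at position 8803115 (hg38, minus strand), 393 nt from the annotated 3′ end of the gene, was not called in U87 and had scores of 81.6, 86.2 and 89.1 in U87-R and 31.6 and 24.0 with STM2457 (limma adjusted p = 0.0469). Without the adjustment, 20706 bases had a p under 0.05, and with the replicate block none passed after adjustment. Leaving out a library moved the count, but it also changed the filter, which then asked for a call in both remaining libraries of that group. Without U87 replicate 1, 2 or 3 it was 3531 (2992 lower in U87-R), 3793 (2800 lower) and 1469 (1155 lower). Without U87-R replicate 1, 2 or 3 it was 0, 5374 (4403 higher) and 1772 (1587 higher). Apart from the 0, most calls were thus higher in the reduced group, so these counts do not separate single libraries from the filter.

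**Figure D1:**
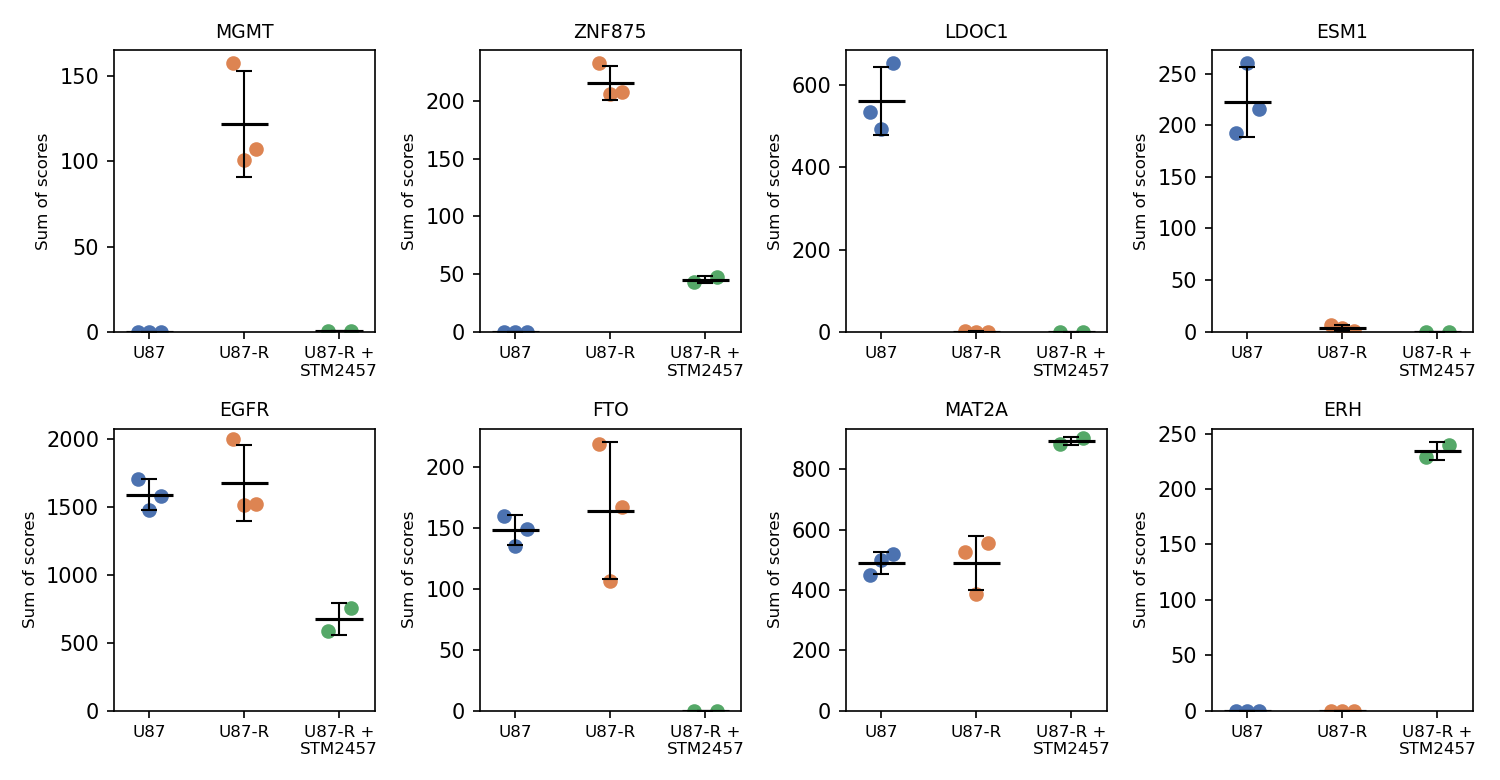
Sum of scores per library for 8 genes in U87, U87-R and U87-R with STM2457; points are libraries, the line is the mean and the bar 1 SD (n = 3, 3 and 2). MGMT and ZNF875 stand near 0 in U87 and high in U87-R, LDOC1 and ESM1 the reverse, EGFR and FTO are lower with STM2457, and MAT2A and ERH are higher.

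The second comparison, STM2457 against DMSO in U87-R, asks what METTL3 inhibition did to the m6A map of resistant cells. Called bases fell in number and in overlap, and the bases that stayed lay closer to the starts of genes. Sums fell in genes of many kinds, among them the early response gene IER3, the chromatin remodelling subunit ARID1A, the matrix protein TNC, the cytokine LIF and the receptor EGFR. MGMT, called in every untreated U87-R library, was almost gone, at 0.253 ± 0.0210 (SD, n = 2). MAT2A, which makes the methyl donor S-adenosylmethionine, rose from 489 ± 90.3 (SD, n = 3) to 894 ± 14.0 (SD, n = 2), while its called bases did not rise in number.

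The number of called bases was 170940 ± 21611 (SD, n = 3) without and 108390 ± 3518 (SD, n = 2) with STM2457, a ratio of 0.634 (exact two-sided permutation p = 0.1, the smallest possible). At bases called in all 8 libraries the median score was 42.6 ± 5.17 and 32.4 ± 0.998 (SD, n = 3 and 2; exact permutation p = 0.2). The authors' list of reproducible sites held 12791 sites with STM2457, from 2 libraries where the other lists had 3. Of the 35207 untreated sites 28.6% were in it, and 78.6% of its own sites were on the untreated list; 2450 were on neither of the other lists. By peaks, 60.4% of the untreated list overlapped 1 of the 50034 treated peaks, and 82.7% of the treated peaks overlapped an untreated one.

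Position mattered for what was lost. Of 46486 bases with a score of at least 10 in all U87-R libraries, 26.6% were absent from both treated libraries and 46.5% kept a score of at least 10 in both. Within 50 nt of the annotated 5′ end of a gene, 1.07% were absent and 92.7% kept, and farther away 30.3% were absent and 40.0% kept. The share of assigned called bases within 50 nt of the 5′ end was 6.29% ± 0.513 in U87, 7.21% ± 0.720 in U87-R (SD, n = 3 each) and 15.8% ± 0.536 with STM2457 (SD, n = 2; exact two-sided permutation p = 0.1 against U87-R, the smallest possible). Their number rose from 10570 ± 267 to 14060 ± 13.4 per library, a ratio of 1.33 (exact permutation p = 0.1).

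**Figure D2:**
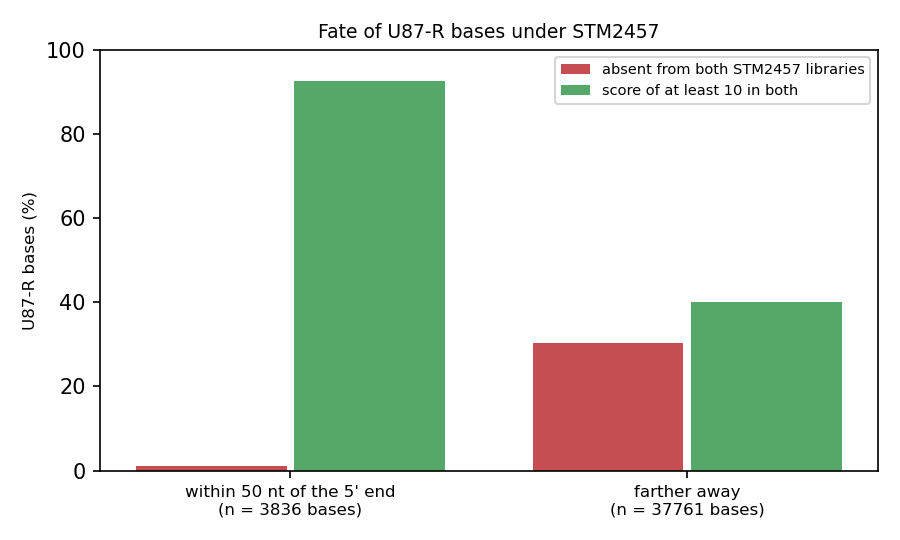
Percent of U87-R bases (score of at least 10 in all 3 U87-R libraries) that were absent from both STM2457 libraries or kept a score of at least 10 in both, by distance from the annotated 5′ end. Within 50 nt 92.7% of 3836 bases were kept, and farther away 40.0% of 37761 bases.

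**Figure D3:**
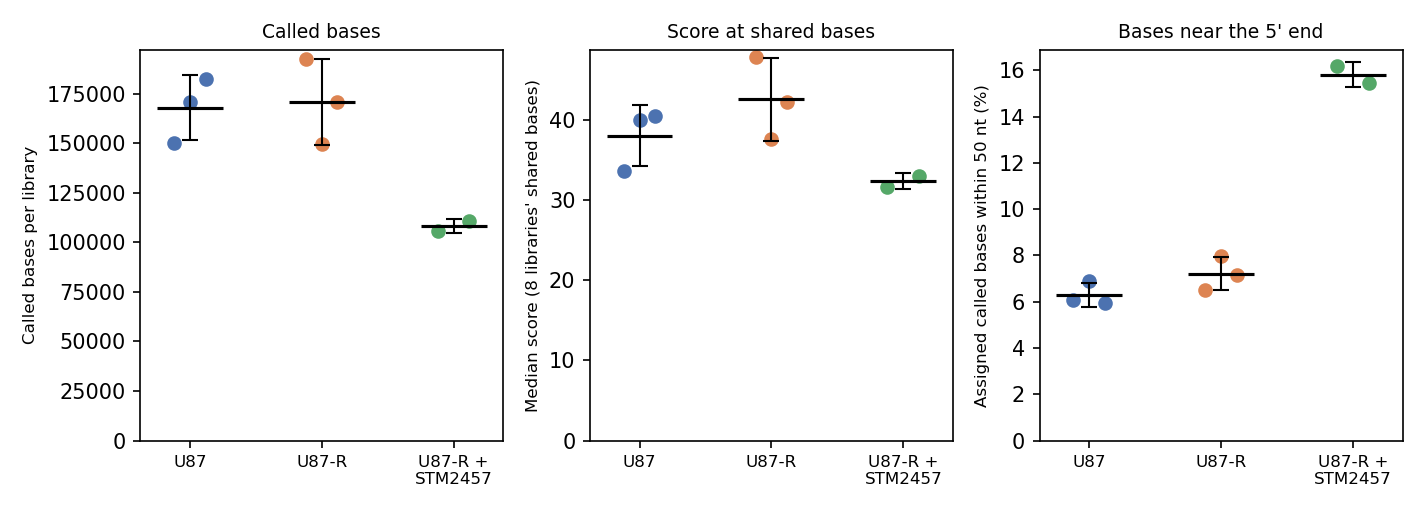
Called bases, median score at bases called in all 8 libraries and percent of assigned called bases within 50 nt of the 5′ end, per library; the line is the mean and the bar 1 SD (n = 3, 3 and 2). The STM2457 libraries hold the fewest called bases and the highest percent near the 5′ end.

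By gene, 3836 of 9835 tested were lower with STM2457 and 554 higher at an adjusted p under 0.05 (limma), and the median change of all tested genes was -0.69 (log2). With each library centred on its median sum, which left a median change of -0.14, 2444 were lower and 1466 higher, and with scaling to library totals 2114 and 1751. The share of higher genes among those called thus went from 12.6% to 37.5% and 45.3%. Leaving out STM2457 replicate 1 or 2 left 1 treated library, and the median change was -0.66 and -0.72 (log2). Genes with a sum of at least 10 in treated libraries alone then failed the filter, which left 9658 and 9664 genes. Such fits cannot show whether the increases hold.

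The largest decreases took sums close to 0. RPL13, a ribosomal protein gene, stood at 524 ± 229 (SD, n = 3) without and 0.035 ± 0.050 (SD, n = 2) with STM2457 (limma adjusted p = 8.25e-06). ATG101, an autophagy gene, stood at 325 ± 37.8 and 0.194 ± 0.274 (adjusted p = 6.39e-06). PLIN3, a lipid droplet coat protein, stood at 273 ± 30.8, the transporter-like gene SLC35F1 at 244 ± 23.2 and RNF7, a ubiquitin ligase subunit, at 240 ± 68.0, and all 3 were listed at 0 with STM2457 (adjusted p = 6.68e-06, 6.68e-06 and 9.9e-06). AMD1, an enzyme of polyamine synthesis, fell by 7.81 ± 0.39 (log2, SE; adjusted p = 6.68e-06) and PDE10A, a phosphodiesterase, fell by 7.90 ± 0.55 (adjusted p = 2.4e-05). The rule also named GPC3, ADGRE3 and KRT86, at 309 ± 54.9, 256 ± 49.1 and 284 ± 155 and listed at 0 with STM2457, but their bases lay on the strand opposite to the known 1, so the values belong to other transcripts.

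Genes with the largest increases were mostly without any called base in U87 and U87-R. With STM2457 the sums (SD, n = 2) were 234 ± 7.97 for ERH, a binding partner of splicing factors, 202 ± 18.5 for the peptidase PEPD, 175 ± 63.2 for CAGE1, 153 ± 6.50 for the small GTPase ARF5, 136 ± 7.94 for DDOST, 131 ± 10.5 for the RNA polymerase subunit POLR2C and 130 ± 42.1 for UQCRB, each listed at 0 in all 6 other libraries (limma adjusted p from 8.82e-05 to 0.000169). UFD1 rose by 7.05 ± 1.02 (log2, SE; adjusted p = 0.000557) and LRRC28 by 7.01 ± 1.21 (adjusted p = 0.00148). The sum given to FRMPD1, 131 ± 19.1 after 0, lay on the strand opposite to the known 1. In ERH, PEPD, ARF5 and POLR2C, 64.6%, 73.6%, 64.5% and 82.8% of the treated sum lay within 50 nt of the 5′ end, while in CAGE1, DDOST, UQCRB and LRRC28 it was 0%. Over all called genes, 41.9% of those higher and 12.5% of those lower with a called base had over 50% of their treated sum there, against 25.0% of all tested genes with a called base.

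Of the 17 gene lists, 5 moved down relative to the other genes by camera, each with an adjusted p of 0.832 with an estimated correlation. Of 22 immediate early and AP-1 genes 18 fell and none rose (adjusted p = 0.000976; 19 adjusted over the list alone). Among them were IER3 from 2028 ± 111 to 526 ± 17.7 and the RNA decay factor ZFP36L2 from 845 ± 100 to 156 ± 22.5 (SD, n = 3 and 2 here and below). Of 38 chromatin regulators 30 fell and 1 rose, also over the list alone (adjusted p = 0.00268). Among them were ARID1A from 1783 ± 224 to 601 ± 98.2 and the histone methyltransferase SETD2 from 763 ± 135 to 217 ± 8.24. Of 35 mesenchymal and matrix genes 23 fell and 1 rose, also over the list alone (adjusted p = 0.00879). Among them was TNC, from 5669 ± 271 to 2025 ± 146. Of 21 glioma stem and progenitor factors 14 fell, also over the list alone (adjusted p = 0.0167), with LIF from 2785 ± 215 to 484 ± 14.3 and ID3 from 134 ± 46.8 to 0. Of 32 genes of receptor tyrosine kinase, PI3K and MAPK signalling 19 fell and 1 rose (22 and 1 over the list alone; adjusted p = 0.0372, but 0.0512 with the replicate number as a block). Among them were AKT2 from 644 ± 103 to 144 ± 1.38, DUSP4, a phosphatase of MAP kinases, from 753 ± 78.3 to 205 ± 3.29 and EGFR by -1.32 ± 0.17 (log2, SE; limma adjusted p = 0.000328). After median centring and after scaling to library totals 3 of these 5 lists passed, those of immediate early genes, chromatin regulators and stem factors. Centred, 13, 22 and 12 of their members fell and 2, 3 and 1 rose, against 10 and 2 of the mesenchymal and 11 and 2 of the receptor tyrosine kinase list.

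The other 12 lists did not pass this test, which does not show that they moved like the remaining genes, and many of their members fell. In the m6A machinery 14 of 23 fell and 1 rose (14 and 2 over the list alone): FTO, an m6A demethylase, went from 164 ± 56.2 to 0, the m6A reader IGF2BP2 from 443 ± 61.6 to 74.5 ± 14.0, and MAT2A rose by 0.89 ± 0.18 (log2, SE; limma adjusted p = 0.00358) while its mean score per called base went from 24.4 to 59.6. METTL3, the target, stood at 187 ± 66.8 and 147 ± 19.2 (adjusted p = 0.541). In DNA repair 7 of 25 fell and 2 rose, also over the list alone: TP53BP1 went from 534 ± 115 to 51.1 ± 0.638 and MGMT from 122 ± 31.2 to 0.253 ± 0.0210. CHEK2, a checkpoint kinase listed at 0 in U87-R, stood at 11.2 ± 8.25. In cell cycle and p53 response 14 of 27 fell and 1 rose (15 and 2 over the list alone), with the cyclin-dependent kinase inhibitor CDKN1B from 383 ± 65.9 to 68.9 ± 8.81, FOXM1 from 838 ± 29.9 to 135 ± 29.8 and CCND2, a cyclin, from 0.521 ± 0.414 to 19.7 ± 3.04. In apoptosis and survival 11 of 21 fell and 1 rose, with BIRC3 from 226 ± 125 to 0, BCL2L1 from 998 ± 16.5 to 431 ± 61.2 and BID from 338 ± 29.6 to 482 ± 18.0. In drug transport and oxidative detoxification 6 of 15 fell and 3 rose, with ALDH1A3 from 539 ± 130 to 94.9 ± 1.17, NFE2L2, the regulator of the oxidative stress response, from 1169 ± 191 to 402 ± 16.0, TXNRD1 from 451 ± 92.3 to 840 ± 63.3 and ABCC4 from 0 to 55.9 ± 21.1. In hypoxia and glycolysis 10 of 18 fell and 1 rose, with EGLN1 from 941 ± 23.4 to 265 ± 30.7, DDIT4 from 2033 ± 74.0 to 836 ± 26.8 and ENO1 from 526 ± 53.5 to 765 ± 3.24. These last 3 counts were equal over the list alone.

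In stress response 11 of 20 fell, with the chaperone HSPA5 from 877 ± 68.2 to 257 ± 6.04 and DNAJB9 from 569 ± 148 to 118 ± 55.1. In interferon and innate sensing 7 of 19 fell, with TNFAIP3 from 1077 ± 114 to 347 ± 87.6 and NFKB1 from 42.9 ± 10.0 to 3.03 ± 0.603. In WNT, BMP and Hippo signalling 12 of 21 fell, with WNT5A from 3316 ± 229 to 852 ± 53.9 and DKK3 from 66.5 ± 11.9 to 0. Of 13 long noncoding RNAs 2 fell and 1 rose: TUG1 went from 3129 ± 523 to 1499 ± 42.4, MALAT1 by -0.96 ± 0.23 (log2, SE; limma adjusted p = 0.00835, but 0.111 after centring) and SNHG12 from 13.2 ± 22.8 to 116 ± 27.1. Of 11 housekeeping and ribosomal protein genes 5 fell, with TUBB from 790 ± 47.2 to 240 ± 17.0 and ACTB from 1230 ± 21.3 to 541 ± 28.4. Of 4 tested markers of other cell types 1 fell, KDR, from 45.6 ± 20.2 to 7.34 ± 10.4. These counts were equal over the list alone, and the calls of the other members that rose, SPARC (180 ± 49.2 to 331 ± 51.8), ERBB2 (3.03 ± 3.08 to 30.3 ± 6.18) and SMARCA4 (156 ± 12.3 to 283 ± 86.9), had adjusted p of 0.0299, 0.0219 and 0.0452.

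Median centring shifted these counts. Centred, 8 fell and 3 rose in the m6A machinery, 4 and 6 in DNA repair, 9 and 3 in cell cycle and p53 response, 9 and 1 in apoptosis, 4 and 4 in drug transport, 7 and 2 in hypoxia and glycolysis, and 6 and 4 in stress response. In interferon and innate sensing 3 fell and 2 rose, in WNT, BMP and Hippo signalling 6 and 1, among long noncoding RNAs 1 and 2, among housekeeping genes 5 and 1, and among markers of other cell types none. By the number of called bases BID turned to -0.71 (log2; adjusted p = 0.0294) and MAT2A to -0.38 (adjusted p = 0.208). SMARCA4 turned to -2.51 (adjusted p = 0.00564) with the authors' sites only.

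Several of these changes, all increases but KDR, were no longer called when a U87-R library was left out. Over all left-out libraries BID ran from 0.475 to 0.587 (log2) and ENO1 from 0.486 to 0.626. Others moved more, SMARCA4 from 0.507 to 1.14, SNHG12 from 4.18 to 6.85 and KDR from -5.43 to -1.46. Without 1 of the STM2457 replicates only 1 treated library is left, so only the change is given. Without replicate 1 it was 4.18 (log2) for CHEK2, 0.740 for SPARC, 3.45 for ERBB2, 0.838 for TXNRD1 and 5.39 for ABCC4. Without replicate 2 it was 1.06 for SPARC, 3.04 for ERBB2, 6.17 for ABCC4, 4.83 for SNHG12 and -1.46 for KDR. Without U87-R replicate 1 the adjusted p was 0.0596 for SPARC, 0.0613 for BID, 0.0878 for SMARCA4 and 0.0544 for SNHG12. Without U87-R replicate 2 it was 0.0744 for SMARCA4 and 0.0643 for KDR. Without U87-R replicate 3 it was 0.0933 for SPARC, 0.062 for ERBB2, 0.0866 for BID, 0.0904 for ENO1, 0.0761 for SMARCA4, 0.0543 for SNHG12 and 0.0726 for KDR.

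At single bases, 31894 of 188742 tested were lower with STM2457 and 12546 higher. The 5 largest decreases, 1 per gene, were bases with scores over 150 in every U87-R library that were not called with STM2457. They lay in TNC (chromosome 9, position 115086127), JUN (chromosome 1, 58781773), DDIT4 (chromosome 10, 72275230), ITGA5 (chromosome 12, 54395844) and CHST14 (chromosome 15, 40472470; all hg38). Those in JUN, DDIT4, ITGA5 and CHST14 lay 982, 806, 583 and 688 nt from the annotated 3′ end of their gene. The largest increases were at bases not called in U87-R, in the ferritin gene FTH1 (chromosome 11, 61967626; scores 131 and 133 with STM2457), 8 nt from its 5′ end. The others were in SERTAD1 (chromosome 19, 40422945; 127 and 118), IER5L (chromosome 9, 129177281; 143 and 104), SLC7A5 (chromosome 16, 87831168; 99.2 and 147) and EXTL2 (chromosome 1, 100874202; 125 and 109), 980 nt or more from theirs. Leaving out STM2457 replicate 1 or 2 left 1 treated library, and the median change of the tested bases was -1.16 and -1.22 (log2). The 14657 bases called in at least 2 libraries of the STM2457 group only then failed the filter, which left 174085 bases. Whether the increases hold cannot be read from such fits. The number of bases that passed was 25199 (23184 lower, 2015 higher) when only sites on the authors' lists were tested.

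The 2 comparisons share the untreated U87-R libraries, so their changes are tied by chance. Across genes, which are not independent replicates, the changes had a Pearson correlation of -0.0315 and a Spearman correlation of 0.0477, where a simulation without effects gave -0.448 and -0.402. The covariance was -0.058 against -0.203 in the simulation, so the observed value lay above that tie. Of the 87 genes higher in U87-R, 27 were lower with STM2457 and 1 was higher, where independent lists would share 33.9 and 4.9. Of the 23 lower genes 2 were lower and 1 higher with STM2457, where independent lists would share 8.97 and 1.3. These differences were not tested, the comparisons share libraries, and genes near 0 in U87-R cannot fall. MGMT, ZNF875 and KLF4 were among the genes higher in U87-R that fell with STM2457 (adjusted p = 0.000186, 0.0151 and 0.00118), whereas DOCK8, ZNF488 and INHBE did not pass (0.391, 0.937 and 0.551). SAT1, lower in U87-R, rose with STM2457 from 0 to 22.8 ± 0.0420 (SD, n = 2; limma adjusted p = 0.00271).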

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

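The tests that weigh the 2 patterns under STM2457 were chosen after the results were seen, apart from the comparison of lost and kept bases within genes, which was written before. Bases that no gene took up stood out in the treated libraries: 17.9% of called bases lay in no gene of their strand with STM2457 (mean of 2 libraries, 18.0% and 17.9%), against 13.5% ± 0.231 in U87-R and 13.8% ± 0.540 in U87 (SD, n = 3 each; exact two-sided permutation p = 0.1 between treated and untreated U87-R, the smallest possible). Their number per library was 19436 ± 587 with STM2457 (SD, n = 2) and 23134 ± 3267 in U87-R (SD, n = 3), so it did not rise, while called bases inside genes went from 147810 to 88952. No explanation was tested for it.

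The loss of called bases under STM2457 was weighed against lower depth, lower transcript abundance and an uneven change that the fit makes by itself. Lower depth alone is argued against by position: of bases with scores of 50 to 200 in every U87-R library, 10.72% of those farther than 50 nt from the 5′ end were absent from both treated libraries, against 0.2372% of those within 50 nt and at most 0.0346% between pairs of U87 libraries over all positions. In 1767 genes a base vanished from both treated libraries while a weaker base of the same gene kept its score, where pairs of U87 libraries gave 132, 168 and 106. Bases with a score of at least 10 in all U87-R libraries vanished far more often under STM2457, however, at 26.61% against at most 1.129% in a pair of U87 libraries. The U87 pairs thus do not show how many such genes lower abundance with a like loss would give. Lower abundance of whole transcripts stays open, as do changes in isoforms or in the ends of transcripts. The within-gene test of limma called 63.73% of 7852 genes under STM2457 and 3.45% between the lines, but a general drop can itself be uneven on the log scale, so unevenness made by the fit stays open. A loss of METTL3-dependent methylation remains a hypothesis, with lower abundance still open for the drop in sums.

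The larger share of bases near 5′ ends under STM2457 was weighed against 2 technical explanations. A mere loss of the other bases is argued against by their number, which was 1.33 times that in U87-R, with both treated libraries above every U87-R library. Reads set free for all remaining bases stay open: bases near the 5′ end were 0.691 higher (median, log2) and 87 mitochondrial bases 0.425 higher, and the difference of 0.266 was within the SD of 0.298 between U87-R libraries. A biological candidate, that these bases are cap-adjacent m6Am, which the antibody may bind and METTL3 does not make, was not tested.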

How the results depend on the processing

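Settings added after seeing the data were median centring, median-of-ratios scaling, the number of called bases, scores of at least 10, the 5′ distances, and for single bases the fit of 2 groups only. Not run were count models and their scaling, coverage thresholds, and everything that needs the sequence motif or transcript regions. The cause of each change given here was not tested. Leaving out a library or fitting 2 groups uses fewer samples, and stricter thresholds or lists leave fewer bases. Leaving out a library also changes which genes and bases pass the filter.

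Genes called between U87-R and U87 (110) were 73 with the replicate block, 71 with the authors' sites only, 67 by the number of called bases, and 55 to 161 when each library was left out; with the other settings they were 74 to 156. The block kept 71 of the 110. Genes called under STM2457 (4390) were 2891 to 4895 when each library was left out and 3813 to 5048 otherwise. With the replicate block, which the labels' numbers allow but the correlations do not back, they were 3820 (463 higher, 3357 lower), and the block for bases gave 34608.

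Bases called between the lines (1) were 0 with the replicate block, 0 with median-of-ratios scaling, 0 with 2 groups only, 54 with the authors' sites only, 968 with a score of at least 10, and 0 to 5374 when each library was left out. Bases called under STM2457 (44440) were 25199 with the authors' sites only and 25035 to 51555 when each library was left out. Beyond the calls named in these sentences and in the results, the block changed no other call of a named gene between the lines.

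The difference in called bases under STM2457 (-62560) was -30620 at or over the median score and -27290 at a score of at least 10. The 5′ share differed by 8.60 percentage points within 50 nt, 4.56 within 10 nt, 10.97 within 200 nt and 14.37 by summed score. The difference in called bases between the lines (3042) ran from -7835 to 13780 when each library was left out.

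The percent of U87-R sites shared with U87 (79.58) was 80.3 in the upper 50% of scores, 72.08 for bases called in at least 2 libraries, 80.18 within 5 bases, and 65.2 to 74.05 for pairs of libraries. The percent of U87-R sites shared with STM2457 (28.56) was 27.39, 33.03, 29.43 and 37.64 to 41.36, and that of STM2457 sites shared with U87-R (78.6) was 75.38, 71.99, 79.67 and 60.98 to 64.45, in the same order. For peaks the 3 percents were 68.48, 30.75 and 59.26 with at least 50% of each peak, and 85.97, 51.71 and 73.87 in the upper 50% of scores.

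Gene lists called between the lines (0) were 1 with fry, the DNA repair list. Under STM2457 (5) they were 0 with an estimated correlation, 16 with fry, which does not compare a list with other genes, 3 with median centring, 3 with scaling to library totals and 4 with the block, without the receptor tyrosine kinase list (adjusted p = 0.0512). The correlation of the 2 comparisons (-0.0315) was -0.1139 over genes called in either and -0.2128 over single bases. The simulation without effects covered all tested genes only, so these last 2 values have no such value to be read against.

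Of named genes between the lines, EGFR (0.07) turned to -0.0297 with library totals, -0.0702 with median of ratios, -0.086 with median centring with or without the block, and -0.0672 without U87-R replicate 1, and ran up to 0.1364 without replicate 2. MAT2A (-0.02) turned to 0.0525 with the authors' sites and 0.0401 at a score of at least 10, and ran from -0.1148 to 0.1455 when each library was left out. Neither passed the threshold in any of these. Under STM2457, by the number of called bases MAT2A turned to -0.3809 (adjusted p = 0.208) and BID to -0.7106 (0.0294), and with the authors' sites SMARCA4 turned to -2.5111 (0.00564). METTL3 (-0.28), never past the threshold, turned to 0.4051 with library totals, 0.4239 with median of ratios, 0.2742 with median centring, 0.3219 with centring and the block, and 0.0398 with the authors' sites. By the number of called bases, calls were also lost by ADRM1, ZNF488, FANCD2, KLF4 and EGLN3 between the lines and by CCND2, BCL2L1, DNAJB9, NFKB1, ACTB, SPARC, ERBB2, ENO1, SMARCA4 and SNHG12 under STM2457. With a score of at least 10, ZNF83, ADRM1, FANCD2, KLF4 and HCAR2 lost theirs between the lines, and SMARCA4, SNHG12 and KDR under STM2457. With the authors' sites, HCAR3, HCAR2 and KLF4 lost theirs between the lines and SPARC, TXNRD1 and ENO1 under STM2457. With 2 groups only, INHBE, KRT86, KLF4 and LINC03125 lost theirs between the lines and SNHG12 and KDR under STM2457. With a pseudocount of 0.1, KRT86, KLF4 and LINC03125 lost theirs between the lines. With every scaling, MALAT1 and KDR lost theirs under STM2457. With the block, SPARC, ERBB2, BID, ENO1, SMARCA4 and KDR lost theirs under STM2457.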

Other observations

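The family and depth tests below were written before their results were seen, while the enrichment test and the splits of the samples were chosen after. Among the 87 genes higher in U87-R, 21 (24.1%) had symbols of the zinc finger family, against 3.53% of the genes tested (Fisher's exact test across genes, odds ratio 9.2, p = 1.57e-12, genes not being independent). Of the 23 genes lower in U87-R, 3 were also of the family, which was not tested. Of the 21, 19 lie on chromosome 19, but the share of all tested members there was not counted. At 0 in all 3 U87 libraries were 16, among them ZNF486 (93.8 ± 33.1 in U87-R), ZNF529 (87.1 ± 17.8), ZNF701 (60.9 ± 20.8) and ZNF229 (47.7 ± 3.48; SD, n = 3). ZNF480 rose from 22.8 ± 12.4 to 230 ± 82.9. With STM2457, ZNF480 stood at 381 ± 6.72 and ZNF701 at 88.7 ± 4.14, neither past the threshold, and ZNF665 fell from 17.6 ± 5.43 to 0.363 ± 0.252 (limma adjusted p = 0.00474). These genes share sequence with each other, and without mapping details reads common to several members cannot be excluded as part of the pattern.

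Deeper U87-R libraries stay open as a cause. All 21 were still called after median centring, but this test could not decide it. Centring moved the median change of all genes only from 0.124 to -0.029 (log2), whereas the 21 changed by 3.34 to 7.67. It also cannot restore bases that were not called. A shift of the whole family is argued against, since the median change of 347 tested members was 0.271 (log2), close to the 0.124 of all genes. The pattern may thus belong to a subset. Whether these RNAs became more abundant or more methylated in U87-R was not tested, since the inputs were not analysed here.

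The split of the 6 libraries into U87 and U87-R gave 110 called genes, and 1 of 10 splits, the real one, gave as many; the highest of the others gave 0. For single bases the real split gave 1, the highest of the others 0, and for gene lists the real split gave 0, a value reached by all 10 splits, with up to 2 lists in the others. Splits that part all 3 same-number pairs, as the real one does, gave no gene, no base and at most 1 list. With 10 splits no share under 0.05 can be had.

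Bases that appeared under STM2457 differed in place from those that vanished. Of 3236 bases absent from all U87-R libraries with a score of at least 10 in both treated libraries, 17.7% of those assigned to a gene lay within 50 nt of its 5′ end. Among the 12372 that vanished, which had a score of at least 10 in all U87-R libraries, it was 0.357% of those assigned to a gene. Of all assigned called bases, 15.8% lay there in treated and 7.21% in U87-R libraries. The bases that appeared were thus close to the general treated share, and those that vanished lay far below that of U87-R.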
